A study of Papio hamadryas with 12 samples.

How the data were processed

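Total RNA from the frontal cortex of 12 fetal baboons was measured, 1 array per fetus. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns and checked on a Bioanalyser, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. Per the submitters' processing notes, GenomeStudio 1.9.0 was used. The labels describe 6 control and 6 nutrient restricted pregnancies, so each array is a separate animal. The version of the array and the organism it was designed for are not given in the sources used here.

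The deposited scanner table holds, per the file headers, the average bead signal of each target on each array, a non-normalised intensity on a linear scale. Whether GenomeStudio subtracted a background is not given in the sources used here, and all signals are above 0. The same table holds a deposited detection p-value per target and array. The authors' processed values, deposited as a separate table, are on a log2 scale, a unit found by setting them against the scanner signals. Of their 22148 rows, 20893 could be matched to a scanner row by values within 0.01 on the log2 scale. For the matched rows the authors' value was log2 of the signal less a constant background of the array, divided by a scale of the array, so that the column medians lay between -0.0005 and 0. Scale, centring and direction were thereby settled. The lowest values lay at a floor between -16.01 and -12.66, and the rule by which the rows were chosen is not given in the sources used here. All 13251 scanner rows past the filter were looked up in this way, and 13237 had a match.

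All choices of the main analysis and its alternatives were made before the data were examined, unless stated otherwise. Signals were corrected and normalised with neqc of limma 3.58.1 in R 4.3.3 (normexp background from the detection p-values, offset 16, quantile normalisation). Targets with a detection p under 0.05 on at least 6 of 12 arrays were kept, 13251 rows. Where an identifier was listed on more than 1 row, the brightest was used, which left 13244 targets. There were 7 such identifiers, and for all 7 both rows differed in the same direction between the groups. Each target was fitted with lmFit and eBayes, with Benjamini-Hochberg adjustment over the tested targets. The comparison of the conditions used all 12 arrays and no covariate. The comparisons within males, within females, of the effect between the sexes and of females with males came from a fit of 4 group means that shared 1 estimate of the spread. The highest Pearson correlation between any 2 arrays was 0.991, so no 2 arrays held identical values.

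A target detected on no array of a group has only a bound there, and its fold was computed against the mean, over those arrays, of the lowest signal counted as detected or of its own signal where that was higher. The share of the sum of squares between groups was tested over all splits of the 12 animals. The correlation of the effects in both sexes was tested over all 400 reassignments of the condition within each sex. Both of these tests were added after the data were seen. A value was called dropped out when its detection p was over 0.5 on 1 array and under 0.01 on the 11 others.

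The rule for naming targets took, per direction, the largest log2 changes among targets past the threshold, filled up by the smallest unadjusted p. Because no gene names are paired with the identifiers in the files, at most 2 targets per direction are named. For the same reason the gene lists fixed beforehand, among them the cytosolic and mitochondrial ribosomal subunits and markers of other cell types, could not be tested, nor could the alternatives that concern lists alone. No slide or scan date was found in the files, so no such batch was tested. The array numbers in the labels run with the condition, all control animals before all nutrient restricted ones.

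The fits were tested on simulated data, in which 200 of the 13244 targets were changed by known amounts. The simulated noise was drawn independently for each target, so any correlation between targets was left out. In the comparison of the conditions, 5 of 137 calls were false. Alternatives changed the background correction, the scaling, the filter, the treatment of repeated identifiers, the covariates, the weights and the moderation, used the authors' values, or left out each animal in turn. Depth in an array is the signal over background: about 28% of targets were above it on each array, and a target near background has a compressed fold change. Joins, further tests and plots used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.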

Results

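Gene expression was measured by Illumina bead array in the frontal cortex of 12 fetal baboons (Papio hamadryas) at 165 days of gestation, near term. The mothers of 6 fetuses were controls and those of the other 6 were nutrient restricted during pregnancy, a model of intrauterine growth restriction. Each group held 3 male and 3 female fetuses. Each array listed 47296 rows, each of them called a target here; 7 identifiers stood on 2 rows, and the brighter of these was tested. The mean signal per array ranged from 237 to 390.7 and the median from 63.5 to 113.6. Between 12560 and 13496 targets per array (26.6% to 28.5%) were detected above background at a detection p under 0.05, 13337 ± 191 (mean ± SD, n = 6) in the control and 13114 ± 352 in the nutrient restricted group. The number of arrays limits the precision of every value below. After the detection filter, 13244 targets were tested. The files do not pair the target identifiers with gene names, so targets are given by identifier, and the ribosomal subunit genes that the study's title concerns were not analysed here as a group.

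The array of control animal 1 stood apart from the others. The 1st principal component of the tested targets held 39.4% of the variance and placed this array at a score of 85.9, with the other 11 between -16.8 and -2.4. Of 7287 targets detected at p under 0.01 on all 11 other arrays, 209 (2.87%) were not detected on control 1, and the highest such number on any other array was 7. The signals of these 209 targets on control 1 ranged from 15.4 to 76.7 with a median of 27, below the median of 63.5 for all targets on that array. Their median on the other arrays was 1017. With dropped-out targets left out, the 1st component held 26% of the variance. Control 1 lay at -44.4, still outside the range of the other 11 arrays, -12.4 to 26.4. Its gap on this score was too small to be flagged by the rule used below.

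**Figure D1:**
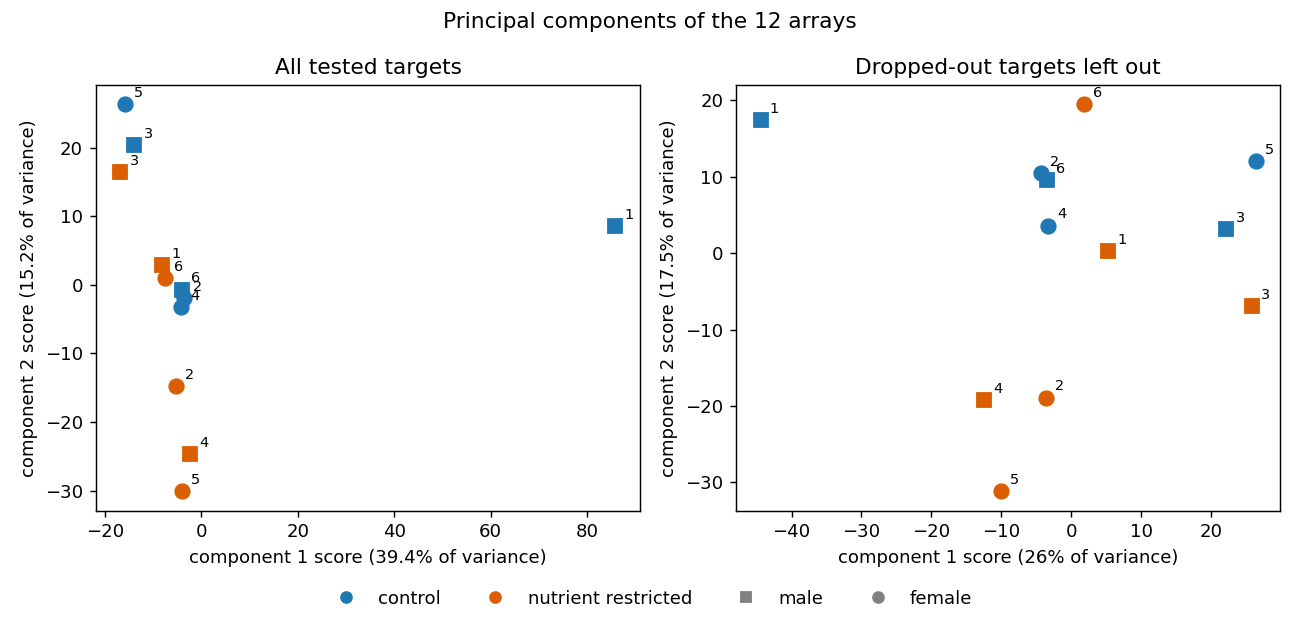
Scores of the 12 arrays on the first and second principal components (arbitrary units, share of variance in the axis labels), coloured by condition, with squares for males and circles for females and the replicate number beside each point. On the left, over all tested targets, control 1 lies at 85.9 on component 1. On the right, without the dropped-out targets, it lies at -44.4.

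**Figure D2:**
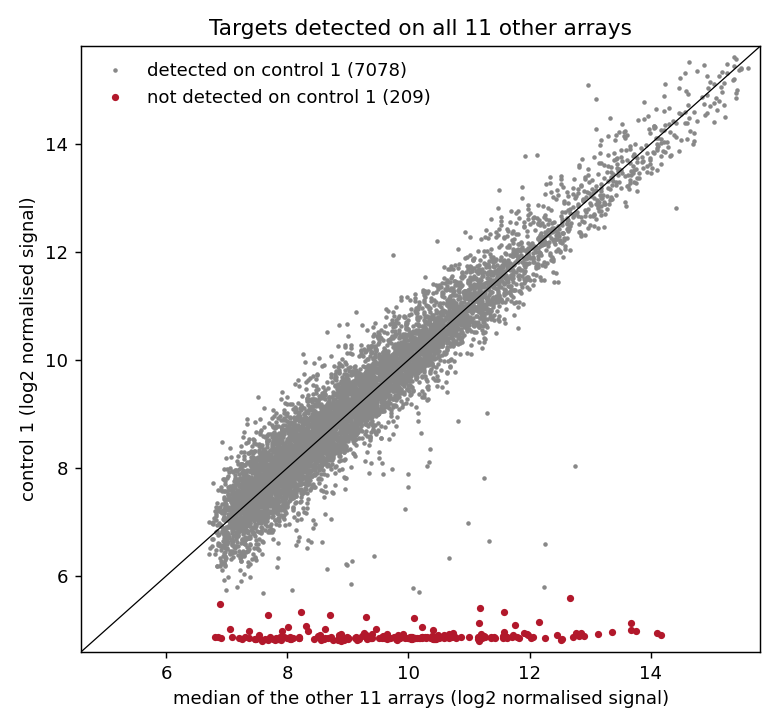
Level on control 1 against the median of the other 11 arrays, both as log2 normalised signal, for the 7287 targets detected on all 11 other arrays. Each point is 1 target, the line marks equal levels, and the 209 targets not detected on control 1 are in red along the bottom.

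The first comparison asked which transcripts differed between the nutrient restricted and the control group. The target GI_38570133-S had the smallest p. Its log2 level was 8.11 ± 0.12 (mean ± SD, n = 6) in the control group and 8.71 ± 0.12 in the nutrient restricted group, a log2 difference of 0.61 (SE 0.10, 1.52-fold). Its level was above every control in 6 of 6 nutrient restricted animals, but it did not pass the threshold (limma adjusted p = 0.245). Without a detection filter it passed (limma adjusted p = 0.0459). The filter came after normalisation, so its levels and difference were unchanged there. Only the moderation of the variances and the adjustment differed. Over the alternatives of the 4 named targets the adjusted p ranged from 0.0459 to 0.761. The next target with a positive difference, GI_41200976-S, had a log2 level of 6.51 ± 0.19 in the control and 7.19 ± 0.24 in the nutrient restricted group (adjusted p = 0.373). In the other direction, GI_22547113-A had 7.87 ± 0.19 in the control and 7.20 ± 0.16 in the nutrient restricted group (log2 difference -0.67, SE 0.11, adjusted p = 0.296), and GI_19549332-S had 7.05 ± 0.25 and 6.40 ± 0.12 (log2 difference -0.64, SE 0.12, adjusted p = 0.373). The values of both groups did not overlap for any of these 4 targets, which were picked by their p in these same data. Over all targets, 69 (0.521%) had groups that did not overlap, where chance gives 0.216% on average. Targets are not independent and this count was not set against other splits of the animals, so an excess over chance was not shown.

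**Figure D3:**
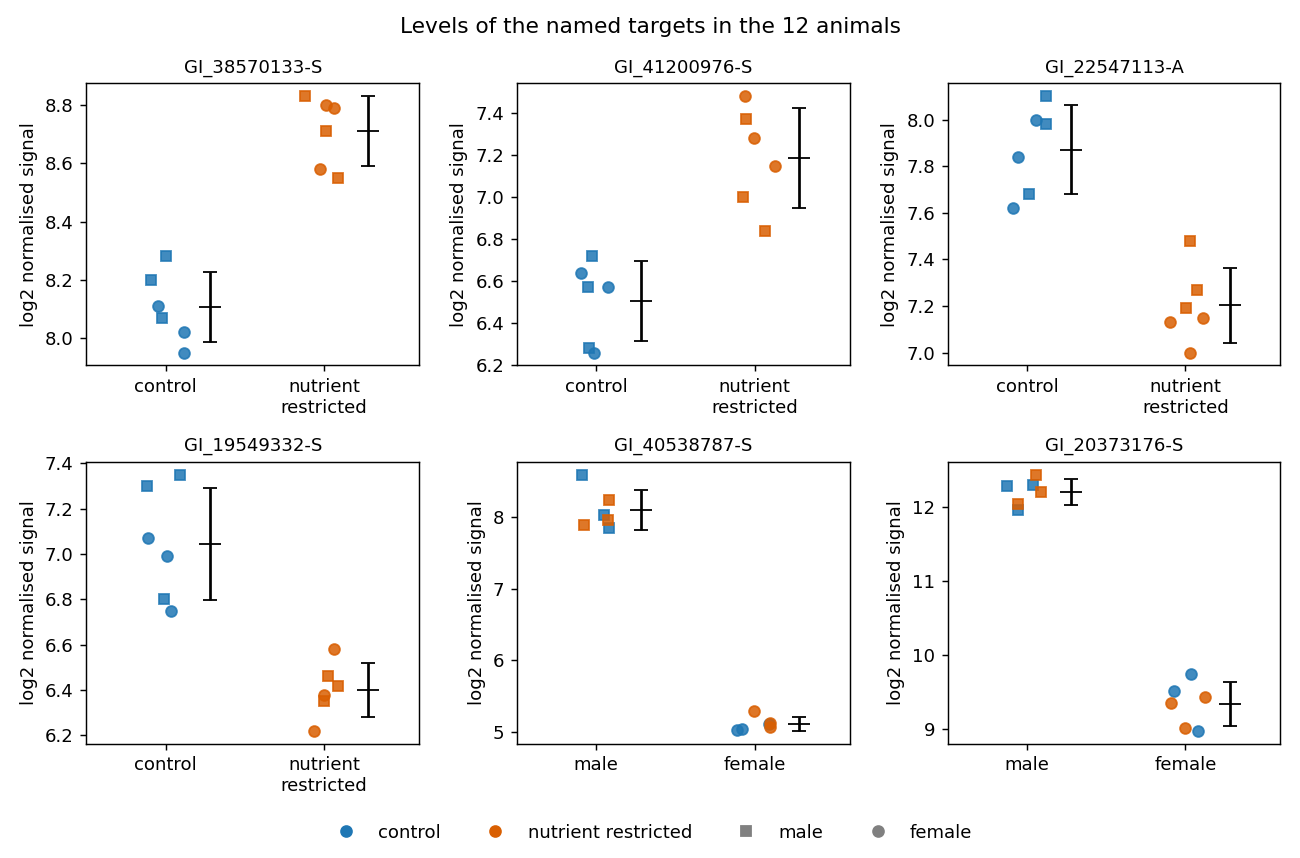
Level of 6 targets in the 12 animals as log2 normalised signal, by condition for the first 4 targets and by sex for GI_40538787-S and GI_20373176-S. Each point is 1 animal (colour for condition, square for male, circle for female), and the bar beside each group is the mean ± SD of 6 animals; vertical axes differ between panels and do not start at 0.

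No target passed an adjusted p under 0.05 between the groups in limma (0 higher and 0 lower, smallest adjusted p = 0.245), and none passed at 0.1. Without a detection filter 1 target, GI_38570133-S, passed as higher, with its levels unchanged. At an unadjusted p under 0.05, 553 targets were higher and 703 lower in the nutrient restricted group, 1256 in all (9.5%), where 662 would be reached at random. This balance moved with the scaling: it was 176 higher and 1074 lower after scaling the arrays to equal medians, and 366 and 1078 on the authors' processed values, which differ in background correction as well as scaling. When 1 animal was left out, the total ranged from 822 (without nutrient restricted animal 5) to 1765 (without nutrient restricted animal 6). The difference between the groups held 10.8% of the sum of squares over all targets (exact permutation p = 0.165, one-sided since a share has no direction, n = 6 per group).

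On the scale of the background-corrected and normalised values, the size of the differences was bounded for most targets. The median standard error of a log2 difference was 0.148, and 95% of the differences lay between -0.44 and 0.49. For 12577 targets (95%) the 95% confidence interval excluded a difference of over 2-fold in either direction, and for 9193 (69.4%) one of over 1.5-fold. Differences of targets near background are compressed on this scale. For such targets the interval bounds the measured difference, and the true one may be larger. A difference of over 2-fold was measured for 63 targets with higher and 4 with lower levels in the nutrient restricted group, and for 366 and 100 on the authors' processed values. The count of 63 rested on control 1: it was 6 without that animal (with 2 lower), between 109 and 114 without any other control animal, and 7 with the dropped-out values set to missing, an alternative chosen after the data were seen. In simulated data with known changes, this comparison recovered 26.9% of log2 changes of 0.5, 76.1% of changes of 1 and 95.5% of changes of 2. That simulation changed 200 targets at once and left out any correlation between targets. Recovery with fewer changed or with correlated targets was not tested.

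The share of targets detected was also counted by identifier class, which compares different probes and not transcript levels. Of 26098 GI targets 44.3% passed the detection filter, against 9.3% of 11622 Hs targets and 6.3% of 9576 hmm targets. At an unadjusted p under 0.05 between the conditions stood 9.9% of the GI targets tested, 6.8% of the Hs and 6.1% of the hmm targets. With the tested targets ordered by signal in 5 groups of about equal size, this share was, from the dimmest to the brightest group, 6.5%, 10.3%, 10.9%, 9.7% and 10%.

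The same question was asked within each sex, with 3 animals per group and the spread estimated over all 12. In males, limma gave 0 targets higher and 0 lower at an adjusted p under 0.05 (smallest adjusted p = 0.867), and 265 higher and 346 lower at an unadjusted p under 0.05. The unadjusted counts in males were 662 higher and 715 lower without control animal 3, and 141 and 177 without nutrient restricted animal 4. Without control animal 6 the higher count was 471, and without control animal 1 the lower count was 171. After scaling the arrays to equal medians they were 286 higher and 182 lower, and on the authors' processed values 190 and 829. Over all alternatives they ranged from 111 to 978 higher and from 171 to 1213 lower, in part because the detection filters changed the number of targets tested. In females, it gave 0 higher and 0 lower (smallest adjusted p = 0.182), and 473 higher and 347 lower at an unadjusted p under 0.05. Without nutrient restricted animal 6 these were 736 and 704, and the lower count was 218 without control animal 4 and 218 without nutrient restricted animal 5. After scaling the arrays to equal medians, the median log2 difference of all targets in females was -0.23, and the unadjusted counts were 109 higher and 1335 lower. Without nutrient restricted animal 3 or 4, both of them males, 1 target passed as higher in females. In simulated data the comparison within males recovered 53.7% of log2 changes of 1 and that within females 50.7%.

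The difference of the effect between the sexes was tested directly. At an adjusted p under 0.05, limma gave 0 targets in which the effect was higher and 0 in which it was lower in females than in males (smallest adjusted p = 0.999), with 196 and 164 at an unadjusted p under 0.05. These unadjusted counts were 424 and 296 without control animal 3, and 122 and 100 without nutrient restricted animal 1. The first was 128 without control animal 1, and the second was 106 without control animal 5, 273 without nutrient restricted animal 2 and 272 without nutrient restricted animal 6. After scaling the arrays to equal medians they were 28 and 609. In simulated data this test recovered 11.9% of differences of 1 on the log2 scale and 69.7% of differences of 2, so that most differences of 1 would be missed with these arrays. Across targets, which are not independent replicates, the effects in males and females had a Pearson r of 0.14 and a Spearman rho of 0.23. Reassigning the condition within each sex gave a two-sided exact permutation p of 0.40 for r (n = 3 per group and sex). When 1 animal was left out, r ranged from -0.01 (without nutrient restricted animal 4, exact permutation p = 0.95) to 0.33 (without control animal 1, exact permutation p = 0.11), and the lowest exact permutation p was 0.06 (r = 0.20, without control animal 5).

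The comparison of the sexes served to check the labels. In females 6 targets were lower than in males and 0 higher at an adjusted p under 0.05 in limma, with 239 lower and 194 higher at an unadjusted p under 0.05. The unadjusted lower count was 158 without control animal 2 and 372 without nutrient restricted animal 2, and scaling to equal medians gave 381 lower and 62 higher. GI_40538787-S had a log2 level of 8.09 ± 0.28 in the 6 males. It was detected on 0 of 6 female arrays, where the measured level was 5.11 ± 0.10, which makes it at least 5.33-fold higher in males (adjusted p = 7.41e-07). That bound sets the mean of the males against the mean, over the female arrays, of the lowest signal that counted as detected. GI_20373176-S was detected on all arrays and its level was 12.19 ± 0.17 in males and 9.34 ± 0.29 in females (log2 difference -2.85, SE 0.15, adjusted p = 2.11e-06). Of the 6 targets, 5 were detected on no female array, and all 6 had levels that did not overlap between the sexes. All 12 animals lay on the side of their labelled sex for the 4 targets with the smallest p, which were chosen by those labels. With detection required on all 12 arrays 1 of these targets was left past the threshold. Without any 1 male animal (control 1, 3 or 6, nutrient restricted 1, 3 or 4) 1 target passed. That is because the filter requires detection on 6 arrays. With the replicate number as a block in the fit, 0 targets passed. Of the 6 pairs of animals with the same number, 4 were of 1 sex. The block fit therefore compared the sexes only within the other pairs.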

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

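All tests of explanations in this part, and the splits of the animals, were chosen or run after the results they bear on were seen. Control animal 1 was the only animal that stood far from the other 5 of its group by the gap to its nearest neighbour. This held on 6 of the 32 sets of 6 values examined. For independent sets chance would give about 5%, or 1.6 sets. These 6 sets are not independent, since they are related measures of the array of control animal 1. The mean signal of its array was 237, against 308.3 to 349.9 in the other controls. Its mean Spearman correlation with the other arrays was 0.80, against 0.862 to 0.88. It had 197 dropped-out targets, against 0 on each of the other controls. Its score on the 1st component was 85.9, against -15.9 to -3.6. With the dropped-out targets left out, that score was examined but not flagged. The spread of its targets around the other arrays was 0.82 on the log2 scale, against 0.26 to 0.35, and still 0.52 with the dropped-out targets left out.

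The 209 targets undetected on control 1 alone have 3 candidate explanations. Absence of the transcripts from that animal would leave their signals among the negative controls, but 85.2% of them had a detection p over 0.95, against 3.95% of targets undetected on all arrays, so their signals lay below those controls. A dimmer array would lose dim targets first, but 4.18% were lost in the brightest of 5 groups of targets by level and 1.65% in the dimmest (Fisher's exact p = 5.8e-05). A failure of one part of the target set may account for them: none of the 333 Hs and hmm targets was lost. At the rate of GI targets of the same brightness 8.59 would be, and the chance of none is 0.000162 for targets lost independently. Both this chance and the Fisher test treat the targets of 1 array as independent, which was not tested. What failed stays open, and the wider spread of the remaining targets on this array was not explained.

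The total of 1256 targets at an unadjusted p under 0.05 between the conditions, against 662 at random, was weighed in the same way. Chance could not be excluded: 7 of 100 splits of the 12 animals, the real one included, gave as many, up to 1922 in another split. The median of the other splits was 491. The dropped-out targets of control 1 are an unlikely source, since the total was 1284 with those values missing, and so is its whole array, since the total was 1343 without it. An effect of nutrient restriction stays open beside chance. The array numbers in the labels put all control animals before all nutrient restricted ones. Whether they mark an order of processing is not given, and such an order could not be told apart from the condition.

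For the other comparisons, the splits gave the following. Within males (611 targets at an unadjusted p under 0.05, 1614 in the highest other split, 5 of 10 splits as large) and within females (820 and 1273, 3 of 10 splits as large), 10 splits are too few for a share under 0.05. For the difference of the effect between the sexes chance could not be excluded, with 360 targets and 1889 in the highest other split (72 of 100 splits as large). For the 6 targets lower in females, 3 of 100 splits, the real one included, were as large. That share is under 0.05 and argues against chance for this count, although the highest other split also gave 6 targets.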

How the results depend on the processing

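The setting of dropped-out values to missing, the share of the sum of squares and the correlation between the sexes were chosen after the data were seen; the other alternatives were planned. Between the conditions, the counts at an adjusted p under 0.05 were 0 higher and 0 lower under every alternative that kept this threshold, with 1 exception: without a detection filter 1 target was higher, GI_38570133-S at an adjusted p of 0.0459. The levels of GI_38570133-S were the same there, since the filter came after normalisation. The adjusted p of the 4 named targets ranged from 0.0459 to 0.761 over their alternatives. Their direction was the same in all 102 combinations of target and alternative. An unadjusted p under 0.05 gave 553 higher and 703 lower. Within males and for the difference between the sexes, all alternatives gave 0 and 0. Within females the higher count ranged from 0 to 1 when 1 animal was left out, and was 0 otherwise. The count lower in females than in males ranged from 1 to 6 when 1 animal was left out (1 without any male, because the filter then leaves out targets detected in 5 males), was 1 with detection required on all 12 arrays, and was 6 under the others except the block. With the replicate number as a block it was 0, and the other counts stayed at 0. Whether the numbers mark pairs of animals was not settled by the values. Of 6 same-number pairs, 2 correlated above 0.1 (r = 0.58 for replicate number 3) and 4 were of 1 sex. The block fit compared the sexes only within the pairs of mixed sex. Of the 6 control animals, 2 correlated best with their own number. At an unadjusted p under 0.05, the counts for the difference between the sexes ranged over all alternatives from 28 to 949 higher and from 62 to 829 lower, and those for females against males from 62 to 982 higher and from 89 to 1021 lower (upper ends without a detection filter, with more targets tested). The share of the sum of squares ranged from 9.3% to 13.2%, with an exact permutation p from 0.0887 to 0.403. The correlation between the sexes ranged from -0.01 (without nutrient restricted animal 4) to 0.33 when 1 animal was left out, and its exact permutation p over all alternatives from 0.06 to 0.95; the cause was not tested. Gene list tests (estimated correlation and rotation test included) and a slide block were not run. Over 2-fold differences numbered 63 higher and 4 lower, 28 and 1 without background correction, 25 and 1 with an offset of 50, 1 and 1 with detection required on all 12 arrays, and 366 and 100 on the authors' values. Scaling to equal medians gave 26 and 4, and array weights 4 and 3. The higher count was 6 without control animal 1, whose dropped-out targets were bright on the other arrays. Signal over background left 13251 of 47296 rows.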

Other observations

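The test in this part was chosen after other results had been seen. A hypothesis was that nutrient restriction shifted the same targets in both sexes. At an unadjusted p under 0.05 in each sex, 35 targets were higher in both, where independent lists would share 9.5, and 30 were lower in both, against 9.1. Opposite directions were found in 1 target (6.9 for independent lists) and in 5 targets (12.4). Both comparisons share 1 estimate of the spread, so the lists are not independent, and how this moves the overlaps was not tested. The correlation of all effects, r = 0.14, had an exact permutation p of 0.40 over 400 reassignments, so that a shared effect may exist but was not shown. With the dropped-out targets left out, r was 0.19 and the exact permutation p was 0.38.

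The difference between the sexes held 8% of the sum of squares over all targets (exact permutation p = 0.701, n = 6 per sex). Most splits of the animals gave a share at least as large. Levels did not overlap between the sexes for 22 targets, where chance gives 28.7 on average. The count of 22 was not set against other splits.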
